A study of Rattus norvegicus with 5 samples.

How the data were processed

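Gene expression was measured in the livers of 4-month-old male rats of 2 inbred strains kept on standard chow. PD, the polydactylous rat strain, is the progenitor. The congenic strain carries a segment of chromosome 4 from the spontaneously hypertensive rat (SHR) on the PD background. The sample labels call it PD.SHR4 and the series text PD.SHR4a. RNA came from 8 rats per strain, and per the labels the labelled cDNA was pooled for each strain before it was hybridised to Affymetrix Rat Exon 1.0 ST arrays. There were 3 PD and 2 PD.SHR4 arrays. Nothing in the labels says that the arrays of a strain held RNA of different rats, so p-values measure only the spread between these arrays, which may be technical, and not the spread between rats.

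The deposited table holds log2 expression values, 1 per probe set and array, for 8797 core-gene probe sets. Per the labels, the authors computed them with RMA in Affymetrix Expression Console, and the submitters' processing notes name RMA and Partek. RMA subtracts background with a model, normalises arrays by quantiles and summarises the probes of a gene robustly. Software versions, the annotation release and the genome build are not given in the sources used here. The values carry no detection calls, so a low value cannot be called absent. Array medians lay between 5.21 and 5.38. The number of arrays limits the precision.

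Probe sets were named through GEO's platform annotation. Of the 8797 probe sets, 7603 had 1 gene symbol, 409 had several and 785 had none in that table. Gene IDs of 7584 of the 7603 matched the RefSeq gene table of assembly GRCr8, which was used for symbols and for the order of neighbouring genes only. No gene was named from a probe set with several symbols, except that the probe set shared by Cd36 and its neighbour Cd36l1 is reported under both names. Where a gene had several probe sets (14 genes), the brightest stood for it, which left 7589 genes.

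The strains were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, PD.SHR4 minus PD, all 5 arrays, no covariate), with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. A second count required a difference of at least 1.5-fold. Standard errors (SE) are those of the moderated fit. The fit was tested on simulated arrays with the PD means, independent noise at the moderated spreads of the fit and 200 changed probe sets. It recovered 12% of log2 differences of log2(1.5), 82% of those of 1 and 100% of those of 2 or 3. Of its 159 calls, 12 were false. The real arrays can miss such differences: the desaturase gene Scd, at -4.35, did not pass (limma, adjusted p = 0.0606).

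Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 31 lists, and again with a correlation estimated from the arrays and with fry. The lists covered lipid, sterol, bile acid, carbohydrate and amino acid metabolism, insulin signalling, xenobiotic and antioxidant genes, sex-dependent genes, the clock, inflammation, interferon, antigen presentation, endoplasmic reticulum stress, the cell cycle, ribosomes, oxidative phosphorylation, gene order around Cd36 and markers of cell types that liver tissue could hold. The share of changed genes among the 50 measured genes nearest to Cd36 was compared with that of all other placed genes by Fisher's exact test.

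Genes were named by a rule: Cd36, the 12 largest rises and 12 largest falls among probe sets with 1 symbol past the threshold whose arrays did not overlap between strains, up to 4 members of each list by smallest p, and up to 8 changed neighbours of Cd36. Other genes are marked as chosen after their values were seen. Probe sets of close paralogues, such as those of the Cyp3a, Oas, Mx and globin families, may bind each other's transcripts, which was not tested. Samples, the tests of the comparisons, lists, alternatives and this rule were fixed before the data were examined. The tests of explanations and of other splits of the arrays were not among these. Alternatives were leaving out each array, the replicate number as a block, no variance shrinkage, an intensity trend with robust shrinkage, leaving out the dimmest 25% of probe sets, quantile normalisation once more, median centring, array weights, other fold limits and neighbourhood sizes, and other list tests.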

Results

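Liver transcript levels were compared between the PD strain and a congenic strain, PD.SHR4, that carries a chromosome 4 segment of SHR, a rat strain deficient in the fatty acid translocase Cd36. The series title sets the comparison against the glucose tolerance and metabolic profile of Cd36-deficient congenic rats. The table held 8797 probe sets on 3 PD and 2 PD.SHR4 arrays, each strain represented by pooled cDNA of 8 males. Array medians ranged from 5.21 to 5.38 on the log2 scale, and lower quartiles from 2.84 to 2.93. Over all probe sets, arrays of the same strain correlated at r = 0.988 to 0.994 (4 pairs) and arrays of different strains at r = 0.986 to 0.987 (6 pairs).

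Cd36, which carries long-chain fatty acids across the cell membrane, was measured first as a check of the labels. The array has a single probe set for it, which also covers the neighbouring paralogue Cd36l1, so the transcripts of the pair were not separated. Its level was 9.11-fold lower in the congenic strain. It measured 7.35, 7.83 and 7.93 in the PD arrays and 4.18 and 4.85 in the congenic arrays, a log2 difference of -3.19 ± 0.26 (SE; adjusted p = 0.0149, limma). The log2 difference was -3.52 to -2.85 over 12 alternative fits, and the adjusted p 2.37e-04 to 0.197. Without PD array 3 the adjusted p was 0.0516, and without congenic array 1 or 2 it was 0.105 or 0.130.

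Across the array, 82 probe sets differed between the strains (limma, adjusted p under 0.05), 58 lower and 24 higher in the congenic strain. All 82 differed by at least 1.5-fold, and 70 by at least 2-fold, and in all 82 the arrays of the strains did not overlap. Chance gives 20% of probe sets without overlap, and 32.1% of all genes had none. At an unadjusted p under 0.05 there were 1211 probe sets, against 440 expected by chance. The lower calls made up 70.7% of the main count, 59.0% after centring each array on its median and 58.0% after a further quantile normalisation. The share fell because more higher calls were made: 59 lower and 41 higher after centring, and 65 and 47 after quantile normalisation. The count was 28 without PD array 1, 55 without PD array 2 and 18 without PD array 3. It was 0 without either congenic array, where a single congenic array was assumed to vary like PD and 737 or 710 probe sets had an unadjusted p under 0.05. All 82 probe sets kept their direction in each of these fits. Leaving out an array could not change it, since their arrays did not overlap between the strains.

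The largest falls were in Ifit1, an interferon-induced antiviral gene (14.7-fold, log2 difference -3.88 ± 0.55 SE), Bmal1, the core clock activator (log2 difference -3.58 ± 0.23 SE), and Insig1, which holds the sterol-regulated transcription factors SREBP in the endoplasmic reticulum (7.97-fold). Next came the antiviral GTPase Mx1 (6.73-fold), Apol3l1 (6.65-fold), Ly6c (6.48-fold) and the acid phosphatase Acp3 (5.74-fold). St8sia1, a ganglioside sialyltransferase, was 5.58-fold lower, and Wfdc21 was 4.90-fold lower from a PD level of 12.4 ± 0.06 (SD, n = 3). Ltc4s, leukotriene C4 synthase, was 4.68-fold lower, the prolactin receptor gene Prlr 4.31-fold lower and the phosphate transporter gene Slc34a2 4.23-fold lower. Adjusted p (limma) ran from 0.00737 for Bmal1, Apol3l1, Wfdc21 and Ltc4s to 0.0489 for Ifit1.

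The largest rises were in Dbp, a clock output transcription factor (16.1-fold, log2 difference 4.01 ± 0.54 SE), and the immediate-early gene Egr1 (7.79-fold). Abcg5, which with Abcg8 forms a transporter that moves sterols into bile, was 5.89-fold higher, the clock gene Per3 5.45-fold higher, and Cyp17a1, the steroid 17-alpha-hydroxylase, 4.85-fold higher. Abcd2, a peroxisomal transporter of very long-chain fatty acyl-CoA, rose 3.79-fold from a PD level of 2.47 ± 0.13 (SD, n = 3), below the lower quartile of every array. Por, the electron donor of microsomal cytochromes P450, rose 3.60-fold and Per2 3.60-fold. Nr1i3, the xenobiotic receptor CAR, rose 3.57-fold, the retinal dehydrogenase Aldh1a1 3.45-fold, the glycosyltransferase Gcnt2 3.14-fold and the insulin-like growth factor binding protein Igfbp2 3.05-fold. Adjusted p (limma) ran from 0.00737 for Per3 to 0.0457 for Dbp.

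**Figure D1:**
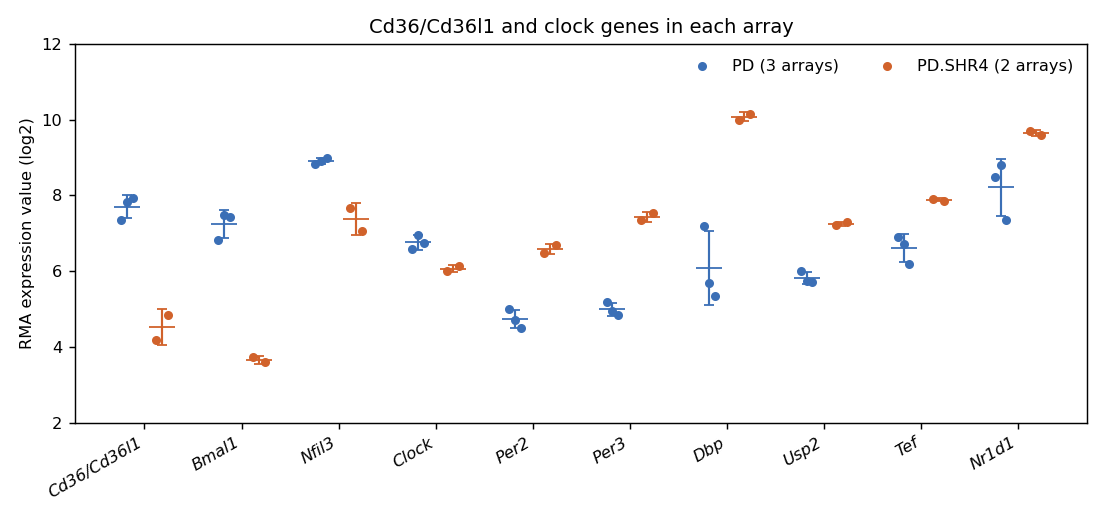
RMA expression values (log2, vertical axis) of the probe set shared by Cd36 and Cd36l1 and of 9 clock genes in the 3 PD arrays (blue) and 2 PD.SHR4 arrays (orange); points are arrays, and bars the mean ± SD. Cd36/Cd36l1, Bmal1, Nfil3 and Clock were lower in both congenic arrays than in every PD array, and Per2, Per3, Dbp, Usp2, Tef and Nr1d1 higher. Clock, Tef and Nr1d1 did not pass the adjusted threshold and, like Usp2 and Nfil3, were chosen after their values were seen.

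Clock genes moved in opposite directions. Of 22 measured members of the clock list, 5 rose, 2 fell and 15 did not pass the test. Bmal1 fell from 7.24 ± 0.37 (SD, n = 3) to 3.66 ± 0.10 (SD, n = 2), while Per3 rose from 4.99 ± 0.17 to 7.43 ± 0.13 and Per2 from 4.74 ± 0.24 to 6.58 ± 0.14. Dbp rose from 6.07 ± 0.98 to 10.1 ± 0.11, and Por, a list member as a clock output, from 8.53 ± 0.15 to 10.4 ± 0.082. The remaining 2 changed members, chosen after their values were seen, were Usp2 (log2 difference 1.44 ± 0.14 SE) and Nfil3, a repressor that opposes Dbp at its sites (-1.54 ± 0.20 SE). Adjusted over the list alone, 9 members rose and 4 fell. As a set the list had a median log2 difference of 0.34 and passed camera (adjusted p = 0.0115), but not with an estimated correlation (adjusted p = 0.394). The set call was also lost without PD array 2 (adjusted p = 0.134) and after median centring (adjusted p = 0.0790), and the median was 0.17 without congenic array 2. Without PD array 1, 2 or 3, the counts were 5, 3 and 2 rises and 1 fall each, and without either congenic array none passed.

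Interferon-induced genes were lower in the congenic strain. Of 28 measured, 7 fell, 0 rose and 21 did not pass the test, and 27 of the 28 values were below 0, with a median log2 difference of -1.37. Ifit1 fell from 9.39 ± 0.99 (SD, n = 3) to 5.51 ± 0.30 (SD, n = 2) and Mx1 from 7.73 ± 0.60 to 4.98 ± 0.18. The immunity-related GTPase Irgm was 3.82-fold lower, the oligoadenylate synthetase-like gene Oasl2 3.35-fold lower and the immunoproteasome subunit Psmb8 2.47-fold lower. There were 24 falls adjusted over the list alone. The set passed camera (adjusted p = 9.28e-23), but not with an estimated correlation (adjusted p = 0.434). Macrophage and Kupffer cell markers were also lower, with a median of -0.44 over 13 genes (camera adjusted p = 1.62e-06; adjusted p = 0.394 with an estimated correlation). None of these markers passed the test singly, and 8 fell when adjusted over the list alone, among them Tyrobp, an immune receptor adaptor (-0.80 ± 0.12 SE), and the macrophage receptor Adgre1 (-0.71 ± 0.16 SE). Without PD array 1 or 3 only 1 interferon-induced gene passed, without PD array 2 6, and without either congenic array 0, while the list's median stayed between -1.51 and -1.15.

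Lymphocyte markers had a median of -0.21 over 18 genes and passed camera (adjusted p = 0.00963; 0.394 as the adjusted p with an estimated correlation). No member passed singly. The cytotoxic cell genes Gzmb, Klrk1 and Prf1 measured -2.01, -1.14 and -0.90 and Cxcr4 measured 0.62, and adjusted over the list alone 7 fell and 1 rose. In the acute phase and inflammation list, 3 of 46 genes fell, 1 rose and 42 did not pass. Those that fell were Hamp, the iron hormone hepcidin (2.46-fold), the cytokine Il18 (2.17-fold) and the plasma protein Orm1 (2.10-fold), and Egr1 rose. Adjusted over the list alone the counts were again 3 and 1. Without PD array 1 none of the 46 passed, without PD array 2 the counts were 2 falls and 1 rise, without PD array 3 0 and 1, and without either congenic array none passed. The median was -0.11 (camera adjusted p = 0.0113; adjusted p = 0.551 with an estimated correlation), and the call was lost without PD array 1 (adjusted p = 0.0806) or PD array 3 (adjusted p = 0.0817).

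Genes of sterol and fatty acid synthesis were lower in the congenic strain, and those of fatty acid oxidation higher. All 21 measured genes of cholesterol synthesis and uptake had values below 0, with a median log2 difference of -0.62. Of these, Insig1 fell (-2.99 ± 0.25 SE; adjusted p = 0.0149) and 20 did not pass the test, among them Dhcr7 (-1.56 ± 0.31 SE), which makes cholesterol in its last step, Cyp51, the lanosterol demethylase (-1.41 ± 0.29 SE), and Insig2 (-1.06 ± 0.20 SE). Adjusted over the list alone, 7 fell. The set passed camera (adjusted p = 1.47e-08) but not with an estimated correlation (adjusted p = 0.534). Of 21 genes of fatty acid and triglyceride synthesis, 20 had values below 0 and none passed the test singly, although 1 fell without PD array 1. Adjusted over the list alone, 4 fell. The stearoyl-CoA desaturase Scd measured -4.35 ± 0.68 (SE; adjusted p = 0.0606) and the desaturase Fads1 -1.59 ± 0.41. This list's median was -0.66 (camera adjusted p = 5.10e-05; adjusted p = 0.551 with an estimated correlation). It was -0.25 without PD array 2 and -1.002 without PD array 1, and the cholesterol list's was -0.38 without congenic array 2, with camera past the threshold each time. Insig1 did not pass without PD array 3 or either congenic array, where its log2 difference remained between -3.24 and -2.75.

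Of 29 measured genes of fatty acid oxidation and ketogenesis, 25 had values above 0, with a median log2 difference of 0.29. None passed the test over all probe sets, although 1 rose without PD array 1, and 13 rose when adjusted over the list alone. Cpt1a, which admits fatty acids to mitochondria, measured 1.37 ± 0.28 (SE; adjusted p = 0.103), the peroxisomal enzyme Ehhadh 1.17 ± 0.18 (adjusted p = 0.0606) and the trifunctional protein subunit Hadhb 0.85 ± 0.12 (adjusted p = 0.0543). The set passed camera (adjusted p = 2.66e-09) and was 1 of only 3 lists that passed fry (adjusted p = 0.0485). It did not pass camera with an estimated correlation (adjusted p = 0.394). The wider list of PPAR-alpha targets did not pass as a set (median 0.085, adjusted p = 0.240). In it, 2 of 25 genes fell, the lipoprotein lipase inhibitor Angptl4 (3.71-fold) and the pyruvate dehydrogenase kinase Pdk4 (2.64-fold), while Ppara, the receptor gene, measured 1.99 ± 0.31 (SE; adjusted p = 0.0606). Adjusted over the list alone, 6 PPAR-alpha targets rose and 3 fell.

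Xenobiotic phase I genes were higher in the median, with 30 of 41 values above 0 and 11 below. Of the 41, 4 rose, namely Por, Nr1i3, Aldh1a1 and the epoxygenase Cyp2j4 (2.72-fold), 37 did not pass and none fell. There were 12 rises adjusted over the list alone. Their median was 0.19 (camera adjusted p = 4.57e-07; adjusted p = 0.534 with an estimated correlation). Without PD array 1 or 3 only 1 of them passed, and without either congenic array 0. In the bile acid list, Abcg5 rose and 23 of 24 genes did not pass, including its partner Abcg8 (0.96 ± 0.14 SE; adjusted p = 0.0514), and 3 rose when adjusted over the list alone. That list's median was 0.19 (camera adjusted p = 0.00318; adjusted p = 0.551 with an estimated correlation), 0.082 without PD array 1 and 0.30 without PD array 2. Abcg5 did not pass without either congenic array.

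Camera passed 2 further lists. Cell cycle genes had a median of -0.46 over 16 genes (camera adjusted p = 9.19e-04; adjusted p = 0.534 with an estimated correlation), and none passed singly; Kif22, a mitotic kinesin, measured -0.71 ± 0.13 (SE) and was the only 1 past the threshold adjusted over the list alone. Erythroid markers had a median of -0.35 over 5 genes (camera adjusted p = 0.0238; adjusted p = 0.534 with an estimated correlation), with Hbb-b1, a beta globin, at -0.66 ± 0.16 (SE) and 1 gene past the threshold adjusted over the list alone. All 5 values were below 0. The median was the value of Hbg1, a dim probe set at 2.84 in PD and 2.49 in the congenic strain, whose arrays overlapped between the strains. The erythroid call was lost without PD array 3 (adjusted p = 0.0867) or congenic array 1 (adjusted p = 0.160), and the median was -0.60 without PD array 1.

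**Figure D2:**
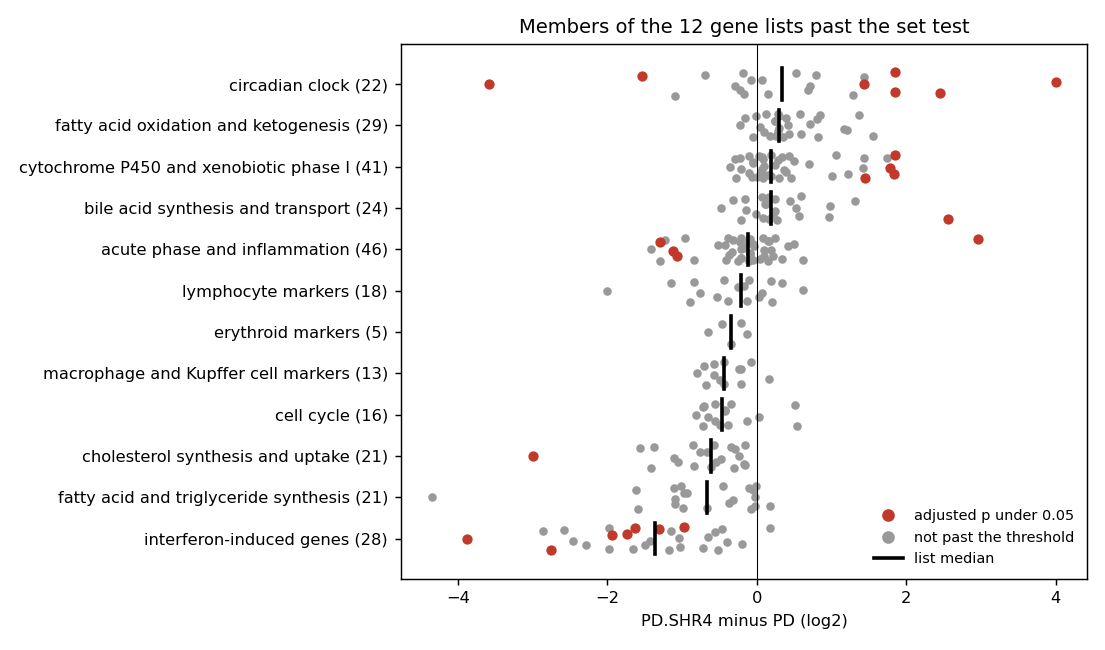
Log2 difference, PD.SHR4 minus PD (horizontal axis), of each measured member of the 12 gene lists that passed camera at the preset correlation; numbers in brackets are measured genes, black bars list medians, red points genes with an adjusted p under 0.05 over all probe sets, and grey points the others. Interferon-induced genes had the lowest median, -1.37, and clock genes spread from -3.58 to 4.01.

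The other 19 lists did not pass camera. Genes of gluconeogenesis, glycolysis and glycogen went both ways, 22 of 41 with values above 0 and 19 below. Their median was 0.017 (adjusted p = 0.666) and none passed singly, with the glucose-6-phosphatase G6pc1 at -1.17 ± 0.31 (SE; adjusted p = 0.174) and the liver glycogen synthase Gys2 at 0.96 ± 0.15 (SE; adjusted p = 0.0606). Insulin signalling had a median of -0.093 over 41 genes (adjusted p = 0.240), with Igfbp2 the single member that rose and none that fell. Fatty acid uptake and activation, without Cd36, had a median of 0.037 over 20 genes (adjusted p = 0.193), and none passed. Lipoprotein genes had a median of 0.025 over 23 (adjusted p = 0.666), and Angptl4 alone fell. Amino acid and urea metabolism had a median of 0.061 over 42 genes (adjusted p = 0.510), oxidative phosphorylation -0.035 over 34 (adjusted p = 0.417) and ribosomal proteins -0.023 over 11 (adjusted p = 0.821). Hepatocyte markers had a median of 0.050 over 12 genes (adjusted p = 0.417), endothelial markers -0.044 over 8 (adjusted p = 0.821), stellate cell and fibroblast markers -0.045 over 18 (adjusted p = 0.362), cholangiocyte markers 0.18 over 9 (adjusted p = 0.461), and neutrophil markers -0.34 over 6 (adjusted p = 0.107). Markers of adipocytes, pancreas and muscle had a median of 0.073 over 26 genes (adjusted p = 0.246). Adjusted over the list alone, 1 gene each rose and fell in the insulin list, 2 each in the amino acid list, 1 rose in the glucose list, 1 fell in the lipoprotein and cholangiocyte lists and 2 fell in the neutrophil list. The means of the glucose, lipoprotein and amino acid lists were below 0 while their medians and camera directions were above it, and ribosomal proteins had a median below 0 with a mean and camera direction above it. After centring each array on its median, the medians of the oxidative phosphorylation, ribosomal, endothelial and stellate cell lists were above 0, as was the endothelial one after a further quantile normalisation.

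No difference in the share of changed genes was detected near Cd36, in a test that rests on 1 changed gene. Among the 50 nearest measured genes on chromosome 4, Pdk4 alone was changed, a share of 2.00%, against 68 of 7520 other placed genes, 0.904% (Fisher's exact test, two-sided, p = 0.368). Over the whole of chromosome 4 the share was 1.25% of 479 genes, against 0.888% elsewhere (Fisher's exact test, two-sided, p = 0.449). Pdk4 did not pass without PD array 1, PD array 3 or either congenic array, at log2 differences of -1.50 to -1.36. The list of genes fixed from the rodent gene order around Cd36, 18 of them measured, had a median of -0.027 and a mean of 0.12, with camera's direction upward (adjusted p = 0.417), and a median of 0.011 after a further quantile normalisation. None of its members passed over all probe sets, and 3 rose and 2 fell when adjusted over the list alone. The falls were Cyp51 at -1.41 ± 0.29 (SE, adjusted p = 0.102) and, chosen after its value was seen, Gnat3 at -0.39 ± 0.11 (adjusted p = 0.190). Gnat3 lay below the lower quartile of every array in both strains, at 2.60 in PD and 2.21 in the congenic strain. Of the rises, the drug transporter Abcb1a measured 0.98 ± 0.16 (SE; adjusted p = 0.0671), the phospholipid transporter Abcb4 0.57 ± 0.15 (adjusted p = 0.175) and the carnitine octanoyltransferase Crot 0.82 ± 0.19 (adjusted p = 0.134).

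**Figure D3:**
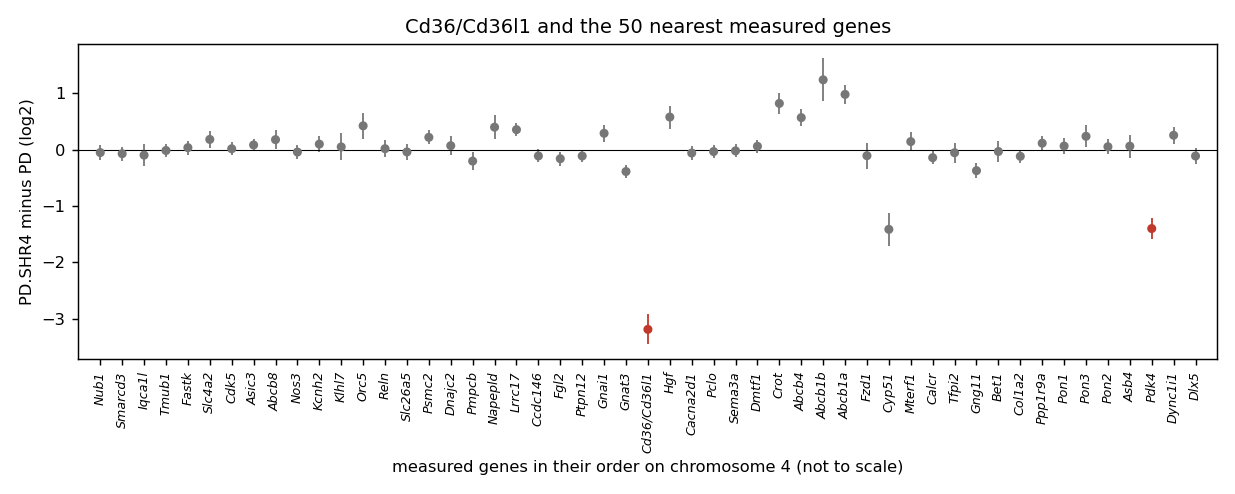
Log2 difference, PD.SHR4 minus PD (vertical axis, bars ± SE), of Cd36/Cd36l1 and the 50 nearest measured genes in their order on chromosome 4 (horizontal axis, not to scale); red marks an adjusted p under 0.05. Cd36/Cd36l1 at -3.19 and Pdk4 at -1.40 are the 2 red points.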

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

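The count over other splits of the arrays was chosen after the result was seen. The 82 changed probe sets kept their direction in every alternative fit that measured them, but their number did not hold. With arrays that did not overlap, leaving 1 out could not change the direction. Leaving out 1 array gave 0 to 55 changed probe sets, and as many past 1.5-fold. No variance shrinkage gave 2, of which 1 was past 1.5-fold and 0 were among the 82, with 1102 at an unadjusted p under 0.05; the intensity trend with robust shrinkage gave 151 and 138; leaving out the dimmest 25% gave 149 and 149, from fewer probe sets tested; and array weights gave 819 and 541. The causes were not tested, except that leaving out a congenic array leaves fewer samples. The fit with the replicate number as a block gave 163 and 163, and 10 lists called by camera. Its arrays share only a number: over probe sets, the difference of arrays 1 and 2 in PD correlated with that in PD.SHR4 at 0.072, so the samples were not taken as paired. Cd36/Cd36l1 ranged from -3.52 to -2.85 with 1 array left out and was -3.19 with no shrinkage (adjusted p = 0.197); over its 12 alternatives the adjusted p ran from 2.37e-04 to 0.197. The share of changed genes near Cd36 ranged from 0 to 12% over 16 alternatives, with Fisher's exact p from 0.0593 to 1; the 12% came with array weights (p = 0.462) and the lowest p with the block, at 6%. Of the 12 lists called by camera, 9 held in all 11 refits, those on acute phase, clock and erythroid genes being the exceptions. With an estimated correlation camera called 0 lists (3 at an unadjusted p under 0.05, adjusted p from 0.394 to 0.551). Fry called 3, those of fatty acid oxidation, the clock and macrophage markers (fry adjusted p = 0.0485 each). The other lists that camera called had fry adjusted p from 0.0538 for lymphocyte markers to 0.282 for fatty acid synthesis, with 0.0675 for interferon-induced genes. The list tests were not rerun without shrinkage or with the trend, the erythroid list had too few genes without the dimmest 25%, and the 100 nearest genes came to 85. Over all alternatives, the 128 other named genes kept their direction and side of the threshold in 1225 of 1534 values, lost the call in 176 and gained it in 133. Only 36 of the 128 were called in the main fit and could lose a call, and 92 were not. The lists kept their side of the threshold in 366 of 402 values, lost the call in 29 and gained it in 7. Here too only the 12 called lists could lose a call, and 19 were not called. The median changed sign in 0 of the values of called lists and in 23 of those of the others. Of the 10 splits of the 5 arrays into 3 and 2, 1 gave as many changed probe sets, the real one with 82; the highest other gave 0, and 10 splits are too few for a share under 0.05. The values carry no signal over background, so the limit that dim probe sets set is unknown.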

Other observations

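The tests of scaling and of collection time for clock genes and of a longer fast were chosen after the results were seen, as were Casp1, Casp4, Ripk3, Il18bp and Abcb1b. Among single genes of no fixed list, 4 that fell are given here with Il18: the log2 difference was -1.13 for Casp1, -1.17 for Casp4, -1.15 for Ripk3 and -1.18 for the Il18 antagonist Il18bp (SE 0.13 to 0.15), beside -1.12 for Il18. In the list of 47 phase II and antioxidant genes, Gclc, the limiting enzyme of glutathione synthesis, was 2.16-fold higher, the haem oxygenase Hmox1 1.95-fold lower, and 45 did not pass; the list's median was 0.0056 (camera adjusted p = 0.609; 2 rose and 1 fell adjusted over the list alone). In the list of sex- and growth hormone-dependent genes, Prlr fell. Hsd17b2 measured 3.06 ± 0.48 (SE; adjusted p = 0.0606), Socs2 -1.35 ± 0.22 (SE; adjusted p = 0.0671) and Cyp3a2 1.74 ± 0.29 (SE; adjusted p = 0.0671). The list's median over 21 genes was -0.15 (camera adjusted p = 0.240; 2 rose and 3 fell adjusted over the list alone). Herpud1 rose 1.79-fold while the endoplasmic reticulum stress list had a median of -0.15 over 26 genes (camera adjusted p = 0.0537; 4 rose and 3 fell adjusted over the list alone), and antigen presentation genes had a median of -0.18 over 21 (camera adjusted p = 0.134; 3 rose and 5 fell adjusted over the list alone). The neighbouring genes Crot, Abcb4, Abcb1b and Abcb1a on chromosome 4 measured 0.82, 0.57, 1.24 and 0.98, none past the threshold.

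Clock genes differed in opposite directions: the 6 measured genes that peak with the Per genes had a median of 1.64 and the 4 that peak with Bmal1 a median of -1.12, a gap of 2.76. Rescaling tested nothing here, on values already normalised. Quantile normalisation once more moved no probe set's log2 difference by more than 0.11. The 1.00 of their difference that the 7 changed clock genes kept, in the median, therefore decides nothing. The median log2 difference over all probe sets was 1.97e-04, but normalisation by quantiles brings it near 0 in any case, so it decides nothing either. The clock genes of both groups moved in opposite directions, whereas a uniform shift would move them the same way. A scaling that shifts all genes of an array alike is thus argued against for these genes, and other forms stay open. Livers taken at different times of the daily cycle would give such a gap, and so would a difference of clock phase between the strains; collection times are not given in the labels, so these cannot be told apart. Dbp also spanned 1.85 on the log2 scale among the PD arrays (SD 0.98, above that of 99.2% of probe sets) and 0.16 between the congenic arrays.

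Interferon-induced genes were lower by a median of 1.37 on the log2 scale. Fewer leukocytes of every type alike are argued against as the whole cause. The 18 macrophage and lymphocyte markers with a mean of at least 5 were lower by a median of only 0.44, 14 below 0 and 4 above. Their median lay 0.93 above that of the interferon list (95% bootstrap interval 0.49 to 1.47, drawn over genes and not arrays). The cytotoxic cell genes Gzmb, Klrk1 and Prf1 measured -2.01, -1.14 and -0.90, and Klrk1 and Prf1 were too dim for this set. Fewer leukocytes of a single type therefore stay open. Rescaling moved the interferon-induced genes too little to test a scaling difference, and the 0.96 of the list's median that it left decides nothing. A difference between the strains, or in the exposure of the pooled animals to infection, stays open and was not tested.

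Sterol and fatty acid synthesis genes were lower and fatty acid oxidation genes higher, a gap of 0.93 between the median of 29 oxidation genes and that of 42 synthesis genes. Rescaling was again too small a change to test a scaling difference, with 0.93 of the gap left by the further quantile normalisation. A longer fast before the congenic livers were taken is argued against only as the single cause, and only by 9 genes picked after the results were seen. Another choice could change their median. The PPAR-alpha list, which also holds Angptl4, Pdk4, Fgf21 and Cpt1a, had 15 values above 0 and 10 below. Its members Ppara (1.99), Ehhadh (1.17) and Acot2 (1.12) were not picked. The 9 picked genes, known to rise in the fasted liver, had a median of -0.61 (95% bootstrap interval -1.40 to -0.017, drawn over genes and not arrays). Of these, 8 were below 0, led by Angptl4 at -1.89 and Pdk4 at -1.40, with Cpt1a alone above 0 at 1.37. Time of day moves many of these genes and could hide a rise, so a longer fast together with it stays open. Time of day by itself and the strain itself stay open too. Scd differed by 2.26 on the log2 scale among the PD arrays (SD 1.13).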
